A study of Mus musculus with 2 samples.

How the data were processed

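The deposited files held 1 count matrix per library, from droplet-based 3' single-cell RNA sequencing of CD45-negative, DAPI-negative cells sorted by tdTomato fluorescence from the bladder of 1 male mouse. Each deposited matrix held raw UMI counts per gene and barcode over 31054 features, including a tdTomato feature, with barcodes already selected as cells by a step that was not stated and with at least 500 UMIs each. Per the submitters' processing notes Cell Ranger 7.0.0 and genome build mm10 were used, while the matrix headers carry software version 3.0.2. No other normalization was found in the values. Gene coordinates were taken from a GRCm38 annotation.

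Cells with at least 1000 UMIs, at least 500 genes and under 15% mitochondrial UMIs passed the filter: 10595 of 13551 Tom- barcodes and 1893 of 2783 Tom+ barcodes. Scrublet, run per library with an expected rate of 0.8% per 1000 cells, called 709 Tom- and 12 Tom+ doublets (6.69% and 0.634%), which were left out. The 9886 and 1881 remaining cells were clustered together without batch integration, using 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, which gave 30 clusters (Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0). Clusters were named from 20 fixed marker lists. A marker counted where at least 25% of the cluster's cells held it. A name needed a mean marker log2 fold of at least 0.5, at least 3 detected markers, and no other class with more markers among the 10 leading genes. Shallow clusters also needed a marker of their own class among those genes. These thresholds were set with the data in hand but before the clusters were seen. Clusters that met no name stayed unnamed, among them 6 and 22, which scored best for fibroblast markers but had Car3, an adipocyte marker, among their leading genes.

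UMIs were summed over the cells of a class in each library and scaled to CPM. Log2 ratios of Tom+ to Tom- were taken after adding 1 CPM, and ratios without it have exact conditional binomial 95% intervals. Sums have exact Poisson intervals and shares exact Clopper-Pearson intervals, and a count of 0 is given with the limit that 3 counts allow or with its Clopper-Pearson upper bound. The 6 classes with at least 50 cells in each library were compared. A gene was measured with at least 10 CPM in 1 library and at least 20 UMIs over both, which 8885 genes met in fibroblast-like cells. A gene under 5% of its level in another class was treated as possible free RNA. For shares of cells with a UMI, each cell was also thinned to 2000 UMIs, which left out 208 Tom- and 78 Tom+ fibroblast-like cells as too shallow. Fibroblast-like cells were clustered again at resolution 0.5, and a second time without tdTomato, Cdkn2a and the named genes. Sub-clusters with at least 30 cells of each library entered equal-weight means.

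Genes were named by a rule: Cdkn2a, Cdkn1a, Cxcl12, Cxcr4 and Ackr3 always, the 12 highest and 12 lowest genes in fibroblast-like cells, and the 5 highest and 5 lowest in each other class, among genes with at least 50 CPM and a UMI in at least 10% of cells in the library where they were higher. Mitochondrial, ribosomal protein and haemoglobin genes, clone-type names, markers of other classes and possible free RNA were left out by the rule, and tdTomato, symbols with more than 1 identifier and a few sex-linked genes were left out in addition. The highest and lowest members of 22 fixed gene lists could be named too. For each list with at least 5 measured members the median log2 ratio was set against 10000 random lists of the same size matched on expression, which describes these 2 libraries only. Members at least 1.5 times higher or lower on the scale with 1 CPM added were counted by size. The comparisons, lists, markers, naming rule for genes and the first set of alternatives were chosen before the data were examined.

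The calculation was tested on simulated data, with folds set in 40 genes per size among 8667 genes. The found log2 ratio lay within 0.25 of the true one for 87.5% to 100% of genes by fold size, the 95% intervals held the true ratio for 95.5% of genes, a raised list stood at percentile 100, and 5 of 100 unchanged lists lay outside the middle 95%. The simulated sums had Poisson noise only, with no variation between cells and with genes varying independently. They therefore check the calculation, and not how well the intervals or percentiles hold in the real data.

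The alternatives were a stricter cell filter (2000 UMIs, 1000 genes, 10% mitochondrial), all barcodes, doublets kept, Leiden resolution 0.5, libraries clustered separately, equal weight per cell, TMM scaling (edgeR 4.0.16), thinning, sub-cluster means at resolutions 0.3, 0.5 and 0.8, removal of 5% free RNA, a pseudocount of 5 CPM, and no filter or a filter of 50 CPM on low values. Added after seeing the data were leaving out barcodes found in both libraries, at least 5000 UMIs per cell, counting clusters 6 and 22 as fibroblast-like, sub-clusters made without the named genes, and leaving out cluster 22 or the deepest mesothelial-like cluster. Cdkn2a in fibroblast-like cells was made a result of its own after its values were seen. Raw reads were not used here, and some genes that met the naming rule are not reported here.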

Results

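Single-cell RNA sequencing compared cells with and without a p16 lineage mark in the bladder of 1 male mouse aged 25 months. The mouse carried a tamoxifen-inducible Cre recombinase under control of p16, a cell-cycle inhibitor encoded by Cdkn2a that is widely used as a marker of senescent cells, and a Cre-dependent tdTomato fluorescent reporter at the Rosa26 locus. Tamoxifen was given on 5 consecutive days, and 2 weeks later live cells lacking the leukocyte antigen CD45 were sorted into a tdTomato-positive library (Tom+) and a tdTomato-negative library (Tom-). The Tom- library held 13551 barcodes with 197232860 UMIs, a median of 10673 per barcode, and the Tom+ library held 2783 barcodes with 34455896 UMIs, a median of 5774. After filtering and removal of predicted doublets, 9886 Tom- cells and 1881 Tom+ cells were used, with median depths of 12773 and 11579 UMIs. Each group was 1 library from the same animal, so no difference has a replicate check, no test between groups was possible, and every 95% interval covers counting error only. Levels are UMIs of a gene scaled to CPM over the summed cells of a class, and ratios are Tom+ over Tom-.

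The first comparison asked which cell classes made up the sorted populations. Fibroblast-like cells were the most numerous class in both libraries, at 44.3% (43.3 to 45.3) of Tom- cells and 38.9% (36.7 to 41.1) of Tom+ cells. Umbrella urothelial-like cells, the superficial layer of the bladder lining, made up 14.1% (13.4 to 14.8) of Tom- and 22.0% (20.2 to 23.95) of Tom+ cells. Lymphatic endothelial-like cells made up 1.98% (1.72 to 2.28) and 4.73% (3.82 to 5.79), and endothelial-like cells of blood vessels 6.95% (6.46 to 7.47) and 9.36% (8.08 to 10.8). The shares of mesothelial-like cells were 7.71% and 8.72%, and those of basal or intermediate urothelial-like cells 6.80% and 8.03%, with overlapping intervals. Barcodes found in both libraries were 11 of 762 Tom- and 67 of 164 Tom+ mesothelial-like cells. They were 112 of 672 Tom- and 55 of 151 Tom+ basal or intermediate urothelial-like cells. Among umbrella urothelial-like cells they were 12 of 1393 Tom- and 71 of 414 Tom+ cells. A share without them is given below for fibroblast-like cells only. Smooth muscle-like cells numbered 60 in the Tom- library and 1 in the Tom+ library, and the 48 Schwann-like and 69 erythroid-like cells were all Tom-, where 0 of 1881 Tom+ cells allows a share of up to 0.159%. The sort on tdTomato fluorescence and the absence of CD45 set all of these shares, which are not shares of the intact tissue. Clusters without a name held 13.9% of Tom- and 7.81% of Tom+ cells, and counting a pair of them that scored best for fibroblast markers as fibroblast-like gave a Tom- share of 52.5%. That pair, clusters 6 and 22, held 671 and 142 Tom- cells but only 18 and 7 Tom+ cells. Counting them therefore widened the difference in this share between the libraries.

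**Figure D1:**
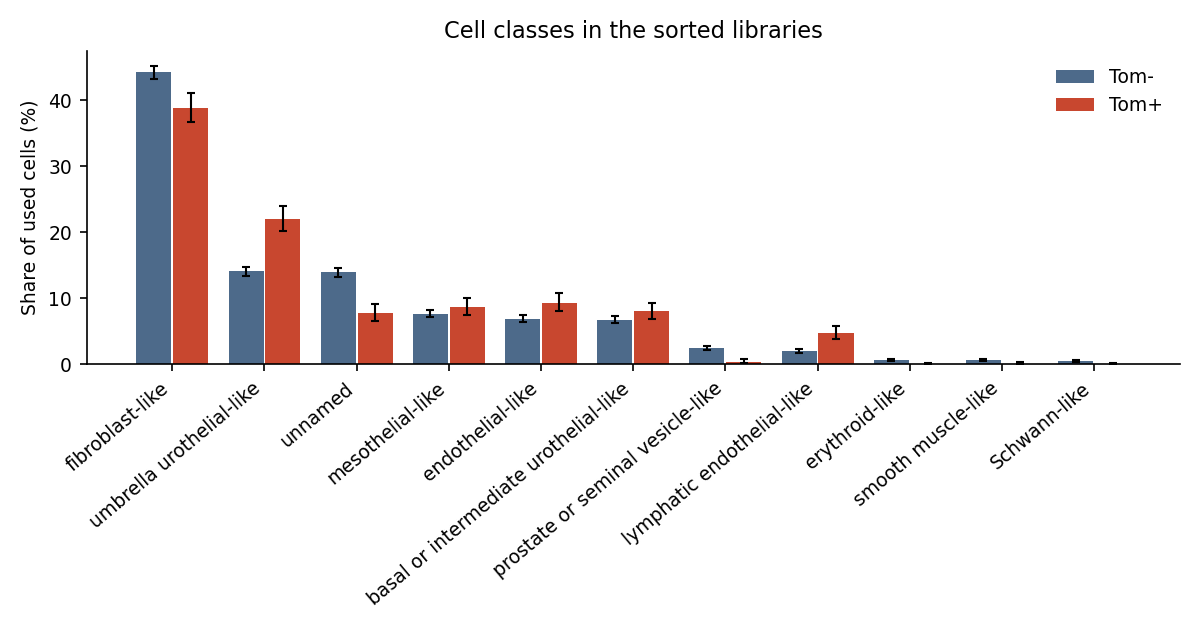
Share of used cells (%, vertical axis) in each cell class for the Tom- and Tom+ libraries, with exact 95% binomial intervals as error bars. Fibroblast-like cells were the largest class in both libraries, and umbrella urothelial-like cells made up 14.1% of Tom- and 22.0% of Tom+ cells.

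The reporter transcript followed the sort over the libraries and in the 6 classes compared. tdTomato stood at 37.4 CPM (36.5 to 38.2) in all Tom- barcodes and at 1214 CPM (1202 to 1226) in all Tom+ barcodes, a ratio of 32.5 (31.7 to 33.3). Among used cells, a tdTomato UMI was found in 31.4% of Tom- cells and 89.3% of Tom+ cells. After each cell was thinned to 2000 UMIs, the shares were 6.62% of 9064 Tom- cells and 83.7% of 1681 Tom+ cells. In fibroblast-like cells tdTomato was 18.1 CPM in Tom- and 1792 CPM in Tom+, and in endothelial-like cells 87.0 and 2031 CPM. In prostate or seminal vesicle-like cells it was 622 CPM in Tom- and 236 CPM in Tom+, the latter from 4 UMIs in 8 cells, a ratio of 0.3803 (0.103 to 0.983). All 8 Tom+ cells and 136 of the 243 Tom- cells of this class carried a barcode found in both libraries. Their ratio therefore cannot be read as a difference between the sorted populations. Gt(ROSA)26Sor, the noncoding transcript of the locus that carries the reporter, was also 3.27 times (2.40 to 4.46) higher in Tom+ than in Tom- endothelial-like cells.

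The next comparison asked whether cells carrying the p16 lineage mark held more Cdkn2a transcript. Over all used cells no difference was detectable at this depth: Cdkn2a was 4.18 CPM in Tom- and 3.61 CPM in Tom+ cells, a ratio of 0.862 (0.704 to 1.05). In fibroblast-like cells Cdkn2a was 1.43 CPM (70 UMIs) in Tom- and 5.77 CPM (38 UMIs) in Tom+, a ratio of 4.04 (2.65 to 6.08). This log2 ratio, 1.48, was 0.21 with each cell thinned to 2000 UMIs, and 0.50 and 0.72 as equal-weight means within sub-clusters made with and without the named genes. Thinning left few Cdkn2a UMIs, so its value is imprecise and cannot show whether depth changes the ratio. In mesothelial-like cells Cdkn2a was 3.64 CPM (61 UMIs) and 6.56 CPM (24 UMIs), a ratio of 1.80 (1.08 to 2.94), but 1 Tom+ cell held 10 of the 24 UMIs and 1 Tom- cell 10 of the 61, which the interval does not allow for. Most of the Tom- transcript, 57.0% of its Cdkn2a UMIs, lay in unnamed cluster 22, whose leading genes were Rbp4, Tnc and Car3 and in which Cdkn2a reached 136.5 CPM. That cluster was singled out after its values were seen, and without it Cdkn2a over all used cells was 1.83 CPM in Tom- and 3.25 CPM in Tom+, a ratio of 1.78 (1.41 to 2.23). It was picked as the cluster with the highest Tom- level, so leaving it out favours a higher ratio. The ratio without cluster 22 therefore does not show by itself that Tom+ cells held more Cdkn2a. Cluster 22 held 142 Tom- cells and 7 Tom+ cells, a Tom+ share of 4.70% (1.91 to 9.44), against 14.3% (13.4 to 15.3) among fibroblast-like cells. The share was also low in cluster 6, which has the leading genes Car3, Tnc, Dkk2 and Cxcl14 in common with cluster 22, at 2.61% (1.56 to 4.10), and in fibroblast-like cluster 5, which has Cxcl14 in common with both, at 2.20% (1.29 to 3.50), where Cdkn2a in Tom- was 5.05 and 1.001 CPM.

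Transcript was rare even where it was higher. A Cdkn2a UMI was found in 0.937% of Tom- and 1.92% of Tom+ fibroblast-like cells, at median depths of 11047 and 7841 UMIs, against 0.718% of Tom- and 0 of 414 Tom+ (upper bound 0.887%) umbrella urothelial-like cells, at median depths of 38950 and 38187 UMIs. The 38 UMIs in Tom+ fibroblast-like cells came from 14 cells, 1 of which held 13. After thinning to 2000 UMIs the shares were 0.480% of the 4169 Tom- and 0.613% of the 653 Tom+ fibroblast-like cells kept. The ratio in fibroblast-like cells depended on clusters 6 and 22 staying outside the class: with both counted as fibroblast-like, Cdkn2a was 8.26 CPM in Tom- and 7.22 CPM in Tom+, a ratio of 0.874 (0.640 to 1.17). Cdkn2a (ENSMUSG00000044303) lies on chromosome 4 from 89274471 to 89294653 on the minus strand of GRCm38, and counting from the 3' end does not separate its p16 and p19 transcripts, which share their last exons.

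**Figure D2:**
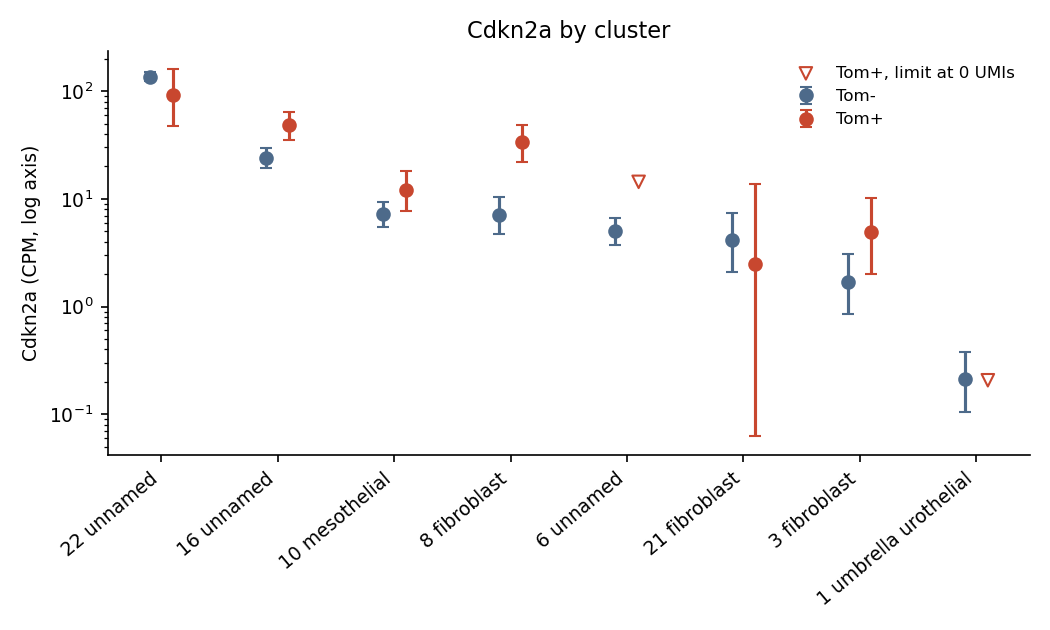
Cdkn2a level (CPM, log axis) per cluster in the Tom- and Tom+ libraries, for clusters with at least 50 Tom- cells and at least 10 Cdkn2a UMIs over both libraries, with exact Poisson 95% intervals; open triangles mark the limit of 3 UMIs where none was counted. The level was highest in unnamed cluster 22, at 136.5 CPM in Tom- and 91.7 CPM in Tom+, the latter from 7 cells.

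Cdkn1a, which encodes the p53-induced inhibitor p21, was 146 CPM in Tom- and 173 CPM in Tom+ fibroblast-like cells, a ratio of 1.18 (1.11 to 1.26). It went both ways within the class, at 1.85 (1.62 to 2.11) in sub-cluster 4 and 0.583 (0.411 to 0.808) in sub-cluster 5 of those made without the named genes. None of the 19 measured cell-cycle inhibitors and senescence regulators differed by 1.5 times in these cells, and their median log2 ratio was 0.06, at percentile 90.2 of 10000 matched random lists. Rb1 was 1.29 times (1.09 to 1.52) the Tom- level and Cdkn2c 0.795 times (0.653 to 0.961). Of 20 measured p53 target genes, 1 was at least 1.5 times lower in Tom+, Plk2 at a ratio of 0.323 (0.254 to 0.406), and none was as much higher. Of 67 measured secretory factors linked to senescence, 3 were at least 1.5 times higher in Tom+ (Cxcl12, Igfbp3 at a ratio of 1.74, and Cd55 at 1.54), 5 were as much lower, among them Igfbp5 at 0.516 and Edn1 at 0.267, and 59 lay between. The list's median log2 ratio was -0.02, at percentile 44.1.

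Fibroblast-like cells were then compared gene by gene, among genes with at least 50 CPM and a UMI in at least 10% of cells in the library where they were higher, without markers of other classes and possible free RNA. Of these, the highest in Tom+ were Gucy1a1, a subunit of the nitric oxide receptor soluble guanylate cyclase, at 121 against 39.0 CPM (ratio 3.11, 2.86 to 3.38), the calcium-activated potassium channel gene Kcnn3 (3.06, 2.72 to 3.45), Dner (2.94, 2.68 to 3.22) and C1qtnf3 (2.68, 2.39 to 3.01). Smoc2 followed at a ratio of 2.11, Matn2 at 1.97, Mn1 at 1.94, the collagen-modifying enzyme gene Plod2 and Itgbl1 at 1.86 each, Cxcl12 at 1.82, the tissue factor gene F3 at 1.74 and the complement component gene C7 at 1.72. The Gucy1a1, Kcnn3 and Itgbl1 differences were not seen within sub-clusters, where their equal-weight mean log2 ratios were -0.10, -0.15 and 0.01. With sub-clusters made without the named genes these means were -0.085, -0.0018 and -0.23. Among the lowest in Tom+ by the same rule were the chemokine gene Cxcl14, at 109 against 535 CPM (ratio 0.204, 0.190 to 0.220), the peptide hormone gene Cck (0.263, 0.220 to 0.312) and Tspan8 (0.3803, 0.321 to 0.448). Asz1, Igfbp5, Ptgs1, Wnt4, Sfrp4, Pla2g7, Spon1 and Basp1 stood at ratios between 0.496 and 0.569. Clusters 3 and 12 held 217 and 135 of the 731 Tom+ cells of the class, while clusters 2, 3 and 4 held 1056, 790 and 791 of its 4377 Tom- cells.

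**Figure D3:**
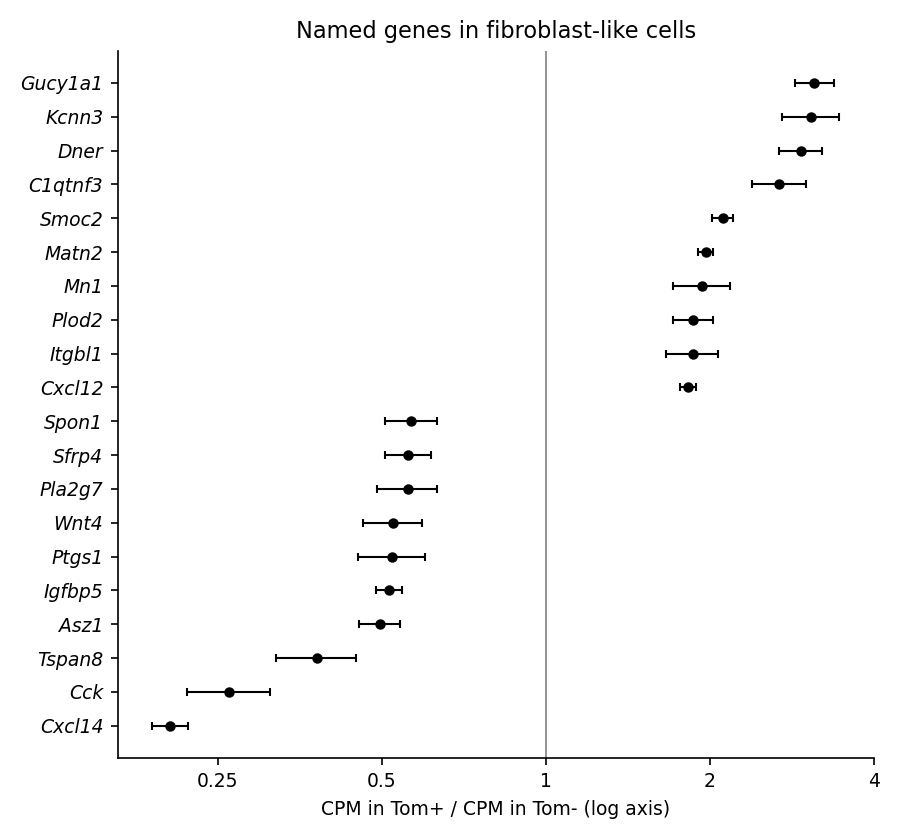
Ratio of CPM in Tom+ to CPM in Tom- fibroblast-like cells (log axis) for the 10 highest and 10 lowest of the genes named by a rule of size, with exact 95% counting intervals. The ratios ran from 0.204 for Cxcl14 to 3.11 for Gucy1a1.

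By gene group, 6 of 55 measured matrix glycoproteins and proteoglycans were at least 1.5 times higher in Tom+ fibroblast-like cells and 2 lower, with a median log2 ratio of 0.15, above all 10000 matched random lists. The higher members included Matn2, Svep1 at a ratio of 1.60 and the proteoglycan gene Lum at 1.55, and the lower were Vit at 0.623 and Spon1 at 0.567. Tissue-resident and perivascular fibroblast genes had a median of 0.25, also above all random lists, but went both ways: of 21 measured, 4 were higher, including Smoc2 and Col15a1 at 1.58, and 3 lower, among them Bmp5 at 0.309 and Car3 at 0.0996. Wnt, Hedgehog and growth factor genes had a median of -0.06 at percentile 5.61, within the middle 95% of random lists, with 1 of 34 higher (Fgf9, 1.68) and 7 lower, including Dkk2 at 0.219, the Hedgehog antagonist gene Hhip at 0.243 and Wnt4 at 0.525. Interferon-stimulated genes had a median of -0.09 at percentile 0.590, with 1 of 31 higher (Ifit3b, 2.497) and 2 lower (Irf7, 0.603, and Rtp4, 0.626). Oxidative stress genes had a median of -0.11 at percentile 0.970, with 2 of 25 lower (Nqo1, 0.574, and Gsta4, 0.560), although Gsta4 in these cells was low enough to be free RNA.

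Of 12 chemokines and receptors, Cxcl12, the decoy receptor gene Ackr2 (1.82) and Cxcl13 (1.60) were higher and Cxcl14 lower, with a median of 0.09 at percentile 94.2. Of 12 complement genes C7 and Cd55 were higher and none lower, with a median of 0.03 at percentile 87.9, and none of 11 antigen presentation genes differed by 1.5 times (median 0.03, percentile 76.5). Col15a1 was higher and Col12a1 (0.639) lower among 20 collagens, whose median was -0.09 at percentile 6.77, with Col1a1 at 0.770. Mmp16 (1.86) was the 1 higher gene of 35 matrix-degrading enzymes and inhibitors, and none was lower (median 0.05, percentile 98.5). Bmp5 and Bmp2 (0.623) were among the lower of 31 TGF-beta, BMP and contractile genes and none was higher (median -0.08, percentile 3.28). Of 21 progenitor and adventitial fibroblast genes Cd55 was higher and Igfbp5 and Wnt2 (0.636) lower (median -0.12, percentile 1.40). Plin4 (1.97) and the retinoid-degrading enzyme gene Cyp26b1 (1.59) were higher and Rbp4 (0.549) and Plin2 (0.658) lower among 24 lipid and retinoid genes (median 0.09, percentile 98.8). Laptm4b (1.53) was higher among 28 lysosome genes and none lower (median 0.04, percentile 95.8). None of 43 dissociation and immediate-early genes, 5 proliferation genes and 28 ribosomal protein genes differed by 1.5 times, with medians of -0.01, 0.06 and -0.10 at percentiles 70.2, 68.0 and 8.62, and of 13 mitochondrial transcripts mt-Nd6 (1.55) was higher (median 0.01, percentile 85.9). Haemoglobin and other erythroid markers, which fibroblasts do not make, were 478 CPM in Tom- and 48.1 CPM in Tom+ fibroblast-like cells, and the 8 measured urothelial genes had a median of -0.75 at percentile 0.01, with 5 lower, among them Krt19 (0.416) at a level low enough to be free RNA.

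The series names secretion of CXCL12, a chemokine that signals through CXCR4, as a feature of senescent bladder fibroblasts, and Cxcl12 was compared in that light. Cxcl12 (ENSMUSG00000061353, chromosome 6 from 117168535 to 117181367 on the plus strand of GRCm38) was 384 CPM (378 to 389) in Tom- and 700 CPM (680 to 720) in Tom+ fibroblast-like cells, a ratio of 1.82 (1.77 to 1.88) and a log2 ratio of 0.87. After thinning, a Cxcl12 UMI was found in 37.5% of 4169 Tom- and 53.9% of 653 Tom+ cells of the class, against 1.01% of 1382 and 0.243% of 412 umbrella urothelial-like cells. The unthinned shares were 70.2% and 74.8% in fibroblast-like cells and 13.1% and 5.56% in umbrella urothelial-like cells. In endothelial-like cells Cxcl12 was lower in Tom+, at 282 against 874 CPM (ratio 0.323, 0.294 to 0.353), and by cluster the ratio was 1.06 in cluster 11, 0.612 in cluster 13 and 0.216 in cluster 20. Over all used cells the ratio was 0.954 (0.927 to 0.983). The receptor gene Cxcr4 was found mainly in endothelial-like cells, at 28.1 CPM in Tom- and 9.29 CPM in Tom+, and the scavenging receptor gene Ackr3 was 189 and 197 CPM in fibroblast-like cells (ratio 1.04, 0.983 to 1.11).

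The Cxcl12 difference was smaller within fibroblast-like sub-clusters than across the class. In sub-clusters made without tdTomato, Cdkn2a and the 24 named genes, sub-cluster 1 (leading genes Gucy1a1, Dner and Adcyap1r1) held 22.8% (21.6 to 24.1) of Tom- and 46.6% (43.0 to 50.3) of Tom+ fibroblast-like cells, and Cxcl12 in it was 1161 and 1417 CPM, a ratio of 1.22. Sub-cluster 2 (Chodl and Ednrb), where Cxcl12 was 144 and 175 CPM, held 21.2% (20.02 to 22.5) of Tom- and 6.43% (4.76 to 8.46) of Tom+ cells. Ratios in sub-clusters 3, 4 and 5 were 1.46, 0.888 and 1.02. The equal-weight mean log2 ratio over these 5 sub-clusters was 0.195, against 0.87 for the class, and giving the Tom- sub-cluster levels the Tom+ mix of cells yielded 597 CPM. The leading genes Gucy1a1 and Kcnn3 of the class had equal-weight means of -0.09 and -0.0018, whereas C1qtnf3 at 0.97, Cxcl14 at -2.76 and Igfbp5 at -0.93 differed within sub-clusters too. Among these 5 sub-clusters Cdkn2a was highest in sub-cluster 5 (Gdf10, Cyp26b1 and Myoc), at 7.02 CPM in Tom- and 32.3 CPM in Tom+, from 26 UMIs in 9 cells and 25 UMIs in 5 cells. Of those 25 UMIs, 13 came from 1 Tom+ cell.

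**Figure D4:**
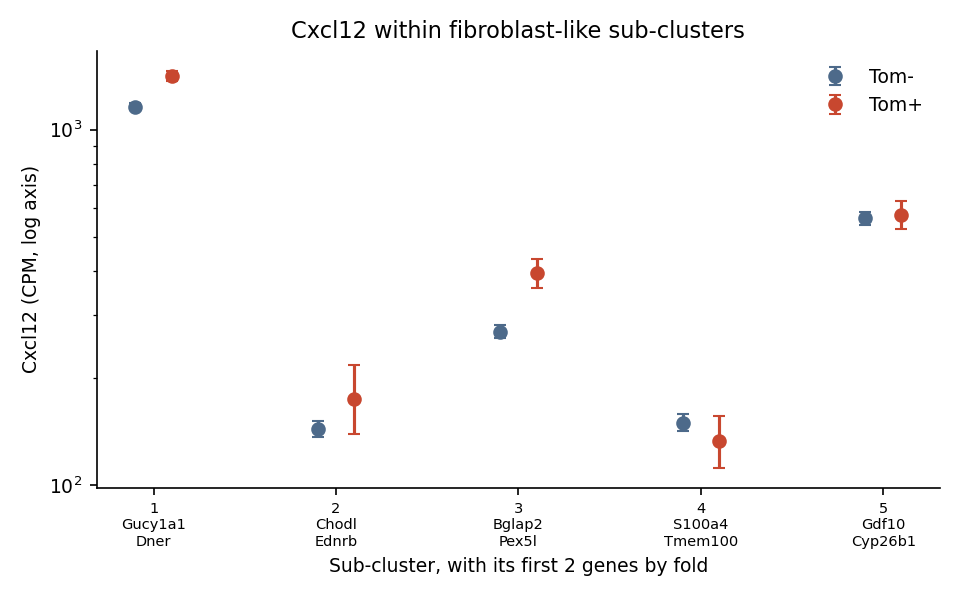
Cxcl12 level (CPM, log axis) in the Tom- and Tom+ libraries within the 5 fibroblast-like sub-clusters that held at least 30 cells of each library, with exact Poisson 95% intervals. The level in sub-cluster 1 was 1161 CPM in Tom- and 1417 CPM in Tom+, above that in every other sub-cluster shown.

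In endothelial-like cells, the lowest genes named by size included Sema3g and Gja4, which are known from arterial endothelium. Sema3g was 88.5 CPM in Tom- and 7.11 CPM in Tom+ (ratio 0.0803, 0.0425 to 0.139), the gap junction gene Gja4 63.2 and 7.65 CPM (0.121), and the Notch target gene Hey1 60.2 and 7.65 CPM (0.127). The interferon-stimulated list had a median log2 ratio of -0.41 in these cells, below all matched random lists and against a median of -0.11 over all 9018 measured genes, with 8 of 34 genes lower and none higher, Cxcl10 at 34.3 against 2.19 CPM. Ribosomal protein genes, a check of depth and RNA quality, had a median of 0.31 in the same cells, above all random lists. Cluster 11, led by the venous genes Selp and Vwf with Lrg1, held 123 of 176 Tom+ and 252 of 687 Tom- endothelial-like cells. Aldh3a1, Aqp3, Gsta4 and Mgst2 were the highest genes named by size after Gt(ROSA)26Sor, at ratios of 2.36 to 2.68, beside basal urothelial markers at 1466 CPM in Tom+ and 750 CPM in Tom-, and Aldh3a1, Aqp3 and Gsta4 were lower in Tom+ when predicted doublets were kept. Fibroblast markers in the class were 1280 CPM in Tom- and 310 CPM in Tom+, and 11 of 13 measured collagens and 10 of 17 adventitial fibroblast genes were at least 1.5 times lower in Tom+.

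In mesothelial-like cells, Prg4, which encodes the lubricant lubricin, was 0.516 times (0.491 to 0.542) and Slpi 0.519 times (0.508 to 0.531) the Tom- level, and Fgf1 0.583 times. Without the deepest mesothelial-like cluster their log2 ratios were -0.80, -0.79 and -0.82. All 3 are among the leading genes of cluster 9, which held 440 of 762 Tom- and 83 of 164 Tom+ cells of the class. Whether the mix of clusters accounts for these differences was not tested. Antigen presentation genes had a median log2 ratio of -0.26, below all random lists, with 5 of 19 lower, including H2-Ab1 at 0.569. Dendritic cell markers, of which Cd74 and H2-Ab1 are also on that list, were 1264 CPM in Tom- and 757 CPM in Tom+ mesothelial-like cells. Mitochondrial transcripts had a median of -0.19 at percentile 0.065 and ribosomal protein genes 0.19 at percentile 100 in this class. Of 15 measured proliferation genes 13 were higher in Tom+, but these rested on few cells: the 77 Mki67 UMIs in Tom+ came from 6 of 164 cells, 1 of which held 38. The largest ratio among genes named by size, 14.0 for Hist1h2ae, rested on 297 Tom+ UMIs of which 1 cell held 142. The urothelial genes Sptssb, Aqp3, Sprr1a and Aldh3a1 were 4.53 to 6.9985 times higher in Tom+. Cluster 30 held 7 Tom- and 10 Tom+ cells with a median of 57748 UMIs and had both mesothelial and urothelial leading genes. The median Scrublet score of its Tom- cells was 0.2018, against at most 0.1108 in every other cluster and a calling threshold of 0.206, so doublets of mesothelial and urothelial cells are not excluded there. Without it the log2 ratios of these genes were 1.52, 0.32, 0.47 and -0.22, with 42 of the 53 Tom+ UMIs of Sptssb and 23 of the 35 of Aqp3 then in 1 cell each, and all 4 were lower in Tom+ when predicted doublets were kept.

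In lymphatic endothelial-like cells, antigen presentation genes had a median log2 ratio of 0.48, above all random lists, with 7 of 17 higher in Tom+ and none lower, among them Cd74 at a ratio of 4.29 (3.23 to 5.71) and H2-Eb1 at 3.57 (2.27 to 5.66). Dendritic cell markers, Cd74 and H2-Ab1 among them, were 106 CPM in Tom- and 396 CPM in Tom+ cells of the class, and fibroblast markers 1434 and 334 CPM. Of 19 p53 target genes, whose median was 0.20 at percentile 94.7, 6 were higher, including Gdf15 at 11.6 (4.67 to 34.4), Phlda3 at 2.58 (1.48 to 4.50) and Cdkn1a at 2.495 (1.91 to 3.26), while the interferon-inducible GTPase gene Iigp1 was 0.251 times the Tom- level. The class held 196 Tom- and 89 Tom+ cells, 39 of the 62 Tom+ H19 UMIs behind the highest ratio among its genes named by size, 7.21, came from 1 Tom+ cell, and 1 Tom+ cell held 9 of the 28 Phlda3 UMIs. In umbrella and basal or intermediate urothelial-like cells the highest ratios among genes named by size were 1.47 for the histone gene Hist1h4d and 1.42 for Gstp1 in umbrella cells and 1.65 for Hist1h1c and 1.55 for Gstp1 in basal or intermediate cells, and the lowest were 0.643 for Sprr2a3 and 0.638 for Peg3. Urothelial plaque and barrier genes had medians of -0.03 and 0.06 in these classes. Lists below all random lists in both were complement (-1.54 and -1.25), collagens (-1.24 and -1.08), matrix glycoproteins (-0.49 and -0.47) and mitochondrial transcripts (-0.18 and -0.24). The complement and collagen genes at least 1.5 times lower, such as C3 and Col1a1, were low enough to be free RNA, and fibroblast markers were 778 CPM in Tom- and 445 CPM in Tom+ umbrella and 1046 and 547 CPM in basal or intermediate cells. Clusters 5, 6, 9, 11, 13, 20, 22 and 30, sub-clusters 4 and 5 for Cdkn1a, Mki67, and list members beyond the highest and lowest of each list were chosen for mention after their values were seen.

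Of the barcodes, 966 occurred in both libraries. For 762 of them the UMI count in Tom+ was a median of 0.335 times that in Tom- (quartiles 0.322 and 0.347), for 198 it was a median of 42.9 times higher (41.0 and 44.9), and 6 were deeper in Tom-. These barcodes were 34.7% of Tom+ and 7.13% of Tom- barcodes, and 346 and 657 of them were among the used cells. Leaving them out, except where 1 copy was over 10 times deeper, gave a Tom- fibroblast-like share of 46.2% and a Cxcl12 log2 ratio of 0.88.

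**Figure D5:**
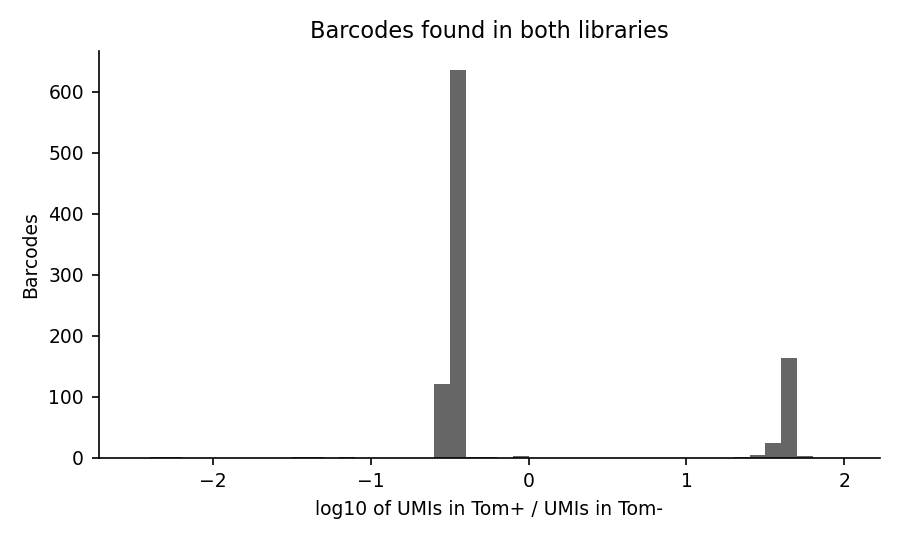
Number of barcodes (vertical axis) by the log10 ratio of their UMIs in Tom+ to their UMIs in Tom- (horizontal axis), for the 966 barcodes found in both libraries. The barcodes fell into a group of 762 with a median ratio of 0.335 and a group of 198 with a median ratio of 42.9.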

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

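The tests of chance barcode reuse, of reads of 1 cell in both libraries, of an outside library, of the mix of fibroblast states, and of free RNA and counting error for Cdkn2a were chosen after the result was seen. Each group was 1 library, so differences between cell classes were not tested.

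Cdkn1a went in different directions by class, with ratios of Tom+ to Tom- of 1.18 in fibroblast-like, 1.67 in mesothelial-like and 2.495 in lymphatic endothelial-like cells, and of 0.853 in basal or intermediate and 0.957 in umbrella urothelial-like cells. Cxcl12 was higher in Tom+ in fibroblast-like cells, at a ratio of 1.82, and lower in endothelial-like (0.323), mesothelial-like (0.446), basal or intermediate urothelial-like (0.470) and umbrella urothelial-like cells (0.402). In these last 3 classes its level was at most 8.59 CPM, where free RNA of other cells is not excluded. The endothelial-like ratio differed by cluster and was not lower in Tom+ in cluster 11, which held 123 of 176 Tom+ and 252 of 687 Tom- cells of the class.

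The Cxcl12 difference in fibroblast-like cells was weighed against the mix of states, depth and shared barcodes. With every cell thinned to 2000 UMIs the log2 ratio was 0.86. CPM is already scaled for depth, so thinning could not decide whether depth played a part. It shows only that the ratio did not rest on the greater weight of deeper cells. Barcodes found in both libraries are argued against, since the log2 ratio was 0.88 without them. The equal-weight mean within sub-clusters was 0.15, against 0.87 for the class, but Cxcl12 was not left out when they were made, which can narrow it. Within sub-clusters made without the named genes it was 0.195. A larger share of Cxcl12-high fibroblasts among Tom+ cells may therefore account for most of the difference. Over the 5 sub-clusters made without the named genes, log2 ratios ran from -0.17 to 0.55. Sub-clusters 1 and 3 had ratios of 1.22 and 1.46 and sub-cluster 4 a ratio of 0.888, so a difference within states stays open. Whether the p16 lineage mark sets the mix was not tested.

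In the data outside the comparisons, Cdkn2a was 136.5 CPM in unnamed cluster 22 of the Tom- library, and only 7 of the cluster's 149 cells were Tom+. Doublets are argued against, because the cluster's median Scrublet score stood at percentile 23.6 of used Tom- cells. The cluster was picked as the one with the highest Cdkn2a level, so a level above that of the library was given by this choice. Only the size of the excess bears on free RNA: the lower bound was 29.5 times the level of all used Tom- cells. That argues against free RNA spread evenly over cells. Counting error does not account for the low Tom+ share, whose upper bound of 9.44% lay below the 14.3% of fibroblast-like cells. The low share is not particular to this cluster, since it was 2.61% in cluster 6, which has Car3, Tnc, Dkk2 and Cxcl14 in common with cluster 22 among its leading genes, and 2.20% in cluster 5, where Cdkn2a was 5.05 and 1.001 CPM in Tom-. No biological explanation was tested, and the time between tamoxifen and sampling, and p19 rather than p16 transcripts, stay open.

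Also outside the comparisons were 966 barcodes found in both libraries, for which chance reuse is argued against as the source of most, since the middle 50% of log10 depth ratios was 0.0495 wide over all 966 and 1.24 wide for random pairs. Within the lower-ratio barcodes, which were chosen by that ratio, it was 0.0265 times as wide as for random pairs. For the 6 deeper in Tom- it was 0.681 wide, and chance reuse stays open. The Tom- library as the only source of the lower-ratio barcodes is argued against too, since 2.03% of its barcodes with at least 3000 UMIs were in the Tom+ library. In 79.0% of shared barcodes the copies correlated better with each other than with the copy of another shared barcode of any kind, which fell between the bounds set for this test. With the other barcode taken from the same kind, a comparison looked at only after that outcome, the share was 90.7% for lower-ratio barcodes and 100% for those deeper in Tom+, both over the 90% set for a fit. The verdict of this test depends on the barcode compared with, so it leaves open whether reads of 1 cell were counted in both libraries. For the 198 barcodes deeper in Tom+, tdTomato in their Tom- copies was 747 CPM, against 35.4 CPM in Tom- barcodes of 1 library only. That argues against separate Tom- cells as the source of these copies, 59 of which were among the used Tom- cells. Prostate and seminal vesicle markers were at least 241 times higher in the lower-ratio barcodes than in barcodes of 1 library, so a library outside these 2 is a candidate source. No biological explanation was tested.

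The Tom- library also held 243 prostate or seminal vesicle-like cells, against 8 in the Tom+ library, and 136 of the Tom- cells and all 8 Tom+ cells carried a barcode found in both libraries.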

How the results depend on the processing

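The alternatives for shared barcodes, 5000 UMIs, clusters 6 and 22, sub-clusters made without the named genes, cluster 22 left out, the deepest mesothelial-like cluster, and all for Cdkn2a in fibroblast-like cells were chosen after seeing the data. In fibroblast-like cells the secretory-list median lay between -0.047 and 0.0071 under every alternative run. The Tom- share of fibroblast-like cells, 44.3%, was 42.8% with the stricter filter, 33.7% with all barcodes (Tom+ 27.5%), 45.9% with doublets kept, 39.2% at resolution 0.5, 38.0% with libraries clustered separately, 46.2% without shared barcodes, 46.0% with at least 5000 UMIs (Tom+ 35.6%) and 52.5% with clusters 6 and 22. The Cxcl12 log2 ratio in fibroblast-like cells, 0.87, was 0.92 with doublets kept, 0.80 at resolution 0.5, 0.94 with clusters 6 and 22 and 0.78 with equal cell weights. As sub-cluster means it was 0.15, 0.20 without the named genes, 0.14 at resolution 0.3 and 0.0673 at 0.8. These means were all positive, but single sub-clusters ran from -0.47 to 0.64 at resolution 0.5 and from -0.37 to 0.41 at 0.8. Cdkn2a in all cells, -0.17, was 0.0912 after thinning and 0.59 without cluster 22, which held 57.0% of its Tom- UMIs. Cluster 22 was picked for its high Tom- level, so leaving it out favours a higher ratio. Cdkn2a in fibroblast-like cells, 1.48, was 1.40 with equal cell weights, 0.21 after thinning, and 0.50 and 0.72 as sub-cluster means with and without the named genes in the clustering. It reversed to -0.17 with clusters 6 and 22, which brings in cluster 22. Of named genes, 3 in endothelial-like cells, 3 in fibroblast-like cells and 4 in mesothelial-like cells reversed under some alternative, and 0 in the other classes. In endothelial-like cells Aqp3 was -0.39 and Gsta4 -0.99 with the stricter filter, and Aldh3a1 -0.74, Aqp3 -1.44 and Gsta4 -1.80 with doublets kept. In mesothelial-like cells with doublets kept Sptssb was -0.56, Aqp3 -0.36, Sprr1a -0.54 and Aldh3a1 -0.54, and Aldh3a1 was -0.22 without the deepest cluster. Within sub-clusters Gucy1a1 was -0.10 and Kcnn3 -0.15, and without the named genes Gucy1a1 was -0.085, Kcnn3 -0.0018 and Itgbl1 -0.23. Apart from cluster 22, the cause was not tested. TMM scaling moved log2 ratios by at most 0.09. No paired analysis was possible because both libraries came from 1 animal and form a single pair. Depth limits Cdkn2a, at 38 UMIs in Tom+ fibroblast-like cells and fewer after thinning, so its thinned values are imprecise.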

Other observations

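tdTomato was 622 CPM in prostate or seminal vesicle-like cells of the Tom- library, above its level in any other class of that library, and 236 CPM in those of the Tom+ library, from 4 UMIs in 8 cells. Cluster 16, unnamed and led by Angptl7, H2-Eb1 and H2-Ab1, had Cdkn2a at 24.1 CPM in Tom- and 48.0 CPM in Tom+, a ratio of 1.99 (1.35 to 2.90). Cluster 8, fibroblast-like and led by Sult1e1, Myoc and Penk, had Cdkn2a at 7.15 and 33.7 CPM, a ratio of 4.71 (2.66 to 8.34). That ratio rests on few cells, which its interval does not allow for. All 38 Tom+ Cdkn2a UMIs of fibroblast-like cells came from 14 cells, 1 of which held 13. Of the 549 cells of cluster 8, 123 carried a barcode found in both libraries. Both clusters were singled out after their values were seen.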
